A study of Mus musculus with 17 samples.

How the data were processed

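RNA of sorted mouse medullary thymic epithelial cells was measured in 17 samples on whole-transcript gene arrays, 1 array per sample. The samples fall into 6 groups by age, Aire genotype and expression of the Igrp-GFP reporter: adult WT GFP- (3), adult WT GFP+ (3), adult KO GFP+ (3), perinate WT GFP- (2), perinate WT GFP+ (3) and perinate KO GFP+ (3). Groups and replicate numbers were taken from the sample labels alone, and arrays are named by the numbers that those give. The deposited values are probe set intensities on a linear scale, which the authors made with Affymetrix Power Tools and RMA (background correction, normalization and summary of the probes of each set), per the submitters' processing notes. The tool versions, any filter of the authors and the set of arrays that were normalized together are not given in the sources used here. Intensities ran from 6.358 to 20106 and none was 0 or negative. The arrays' distributions were close but not identical, with medians of 144.5 to 157.1.

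All 24922 probe sets of the deposited table were read, and 0 columns of values went unused. The platform annotation gave 1 gene symbol to 21425 probe sets, several to 1399 and none to 2098, which are unnamed here, not without a gene. Symbols were checked through the Entrez numbers against the mouse RefSeq annotation of assembly GRCm38.p6, where 21347 of them were found, and 0 symbols had to be updated. That annotation served otherwise only to find the neighbours of Aire along its chromosome, by their start positions. The single-symbol probe sets name 19752 genes. For the 827 genes with several, the probe set with the highest mean over the 17 arrays was used. Values were put on the log2 scale with no pseudocount. A gene was tested if its probe set lay above the 40th percentile of its array on at least 2 arrays, which left 13842 genes. Probe sets with several symbols or none entered no comparison of genes and were fitted separately for the closing observations.

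Every comparison came from 1 linear model of the 6 group means over all 17 arrays, fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), and all p-values of single genes are two-sided and from limma's moderated test, adjusted by the Benjamini-Hochberg method over the 13842 genes within a comparison. Genes with an adjusted p under 0.05 were called. The 9 comparisons were KO against WT GFP+ cells in adults and in perinates, the difference of these effects between the ages, GFP+ against GFP- cells in adults and in perinates, the difference of these, and perinates against adults within WT GFP+, WT GFP- and KO GFP+ cells. Differences are perinate minus adult, KO minus WT and GFP+ minus GFP-. Fold changes come from mean log2 intensities, while the levels given with an SD are means of the linear intensities.

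The number of arrays limits the precision. The model had 11 residual degrees of freedom, and the prior of limma added 5.52. The median standard error of a log2 difference was 0.13 between groups of 3 arrays, 0.145 where perinate GFP- cells entered and 0.184 for the difference of KO effects between ages. The steps were tested on simulated data, in which 200 of 13842 genes were changed by known folds. At 1.5-fold, 2-fold and 4-fold the model called 50.7%, 94% and 98.5% of the changed genes for KO in adults (with 8 calls among unchanged genes), and 64.2%, 92.5% and 100% for KO in perinates (10 calls). For age in WT GFP+ cells it called 49.3%, 91% and 100% (9 calls), for age in KO cells 67.2%, 91% and 98.5% (9 calls) and for age in GFP- cells 41.8%, 88.1% and 100% (5 calls). For GFP+ against GFP- cells it called 76.1%, 97% and 98.5% in adults (11 calls) and 55.2%, 89.6% and 100% in perinates (7 calls). The tests of a difference between ages were less sensitive: 17.9%, 74.6% and 98.5% for the KO effect (4 calls) and 20.9%, 70.1% and 97% for the GFP effect (2 calls).

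The 31 gene lists hold 413 genes, of which 311 were tested. For each list and comparison the members that passed were counted, over all genes tested and again adjusted over the list alone. The 28 lists with at least 5 tested genes were tested with camera, which compares a list with the other genes, at a preset correlation between genes of 0.01, and the p-values were adjusted over all 252 pairs of list and comparison. The test was repeated with the correlation estimated from the residuals and with fry, whose p-value says whether a list's members move on balance one way and does not compare them with other genes. The overlap of lists of called genes was tested with Fisher's exact test and set beside the overlap of independent lists. For the age difference of Aire-dependent genes, whose choice shares arrays with the age comparison, 50 simulations without any age effect, a test added after the result was seen, gave the value that the choice alone produces.

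The genes named were set by a rule written before the data were examined, like the lists and the comparisons with their tests and thresholds. For each comparison it takes Aire and G6pc2 whatever their p. It also takes the 8 largest increases and the 8 largest decreases among called genes with 1 symbol and non-overlapping groups (which the tests of differences between ages do not need), leaving out predicted genes, RIKEN clones, microRNAs and small nucleolar RNAs. By chance, 10% of genes have non-overlapping groups of 3 arrays each. Of each list it takes up to 3 called members with the largest change and the uncalled member with the highest level. The text leaves out some of these, from the smallest change upward within each part of the rule, along with near-identical members of a family, and gives some lists by their counts alone. Uty, Kdm5d, Eif2s3y, Xist, Bpifa2, Bpifa1 and Car6 fall outside the rule and were chosen after their values were seen.

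Replicate numbers recur across groups, and the main design had no block. Arrays of adult GFP- and GFP+ cells with the same number deviated together from their group means (correlations across genes of 0.503, 0.442 and 0.188), so those numbers, which the labels do not explain, were taken to pair the samples, and the fit with the number as a block was made as an alternative. The labels do not name an array date or batch. Alternatives were another filter on dim probe sets or none, repeated quantile normalization, centring on the median, a pseudocount of 16, array weights, trended and robust moderation, every probe set on its own, only the compared groups in the fit, a threshold of 2-fold, the replicate block and leaving out each array in turn. Python 3.11.15 with matplotlib 3.10.9 drew the plots.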

Results

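Gene expression was measured in medullary thymic epithelial cells, the stromal cells that display self-antigens of other tissues to developing T cells. Aire encodes the transcriptional regulator behind much of that ectopic expression. In the C57BL/6 mice the Aire gene drove a reporter, a fusion of Igrp (the product of G6pc2) and GFP, and Aire-knockout cells expressed it too. Epithelial cells that were CD45-negative, Ly51-negative and high in MHC class II were sorted into GFP-positive (GFP+) and GFP-negative (GFP-) cells from adults of 5 weeks or from perinates. The sample labels put the perinates at 3 days and the series text at 0 to 3 days. Wild-type (WT) adults gave 3 GFP- and 3 GFP+ samples, WT perinates gave 2 GFP- and 3 GFP+ samples, and Aire-knockout (KO) adults and perinates gave 3 GFP+ samples each. These 17 samples, all labelled as of mixed sex, were each hybridised to a whole-transcript mouse gene array. The median linear intensity of an array lay between 144.5 and 157.1, and 13842 genes were bright enough to be tested. Intensities below the 40th percentile of an array, which lay between 96.16 and 112.1, are close to background, so a fold change against such a level depends on that floor and on the number of arrays. The labels do not say whether replicates came from separate animals or pools, so p-values here measure only the spread between these samples, which may be technical.

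The groups separated on the main axes of variation. The first principal component held 39.8% of the variance and ordered the cells from GFP- through WT GFP+ to KO GFP+, with group means of -51.9 in perinate GFP- cells, 9.9 in adult WT GFP+ cells and 39 in adult KO cells. The second held 28.8% and placed perinates below adults of the same sort and genotype. Across genes, arrays of one group correlated at 0.9859 to 0.9967 and arrays of different groups at 0.9119 to 0.9842 (genes are not independent replicates).

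**Figure D1:**
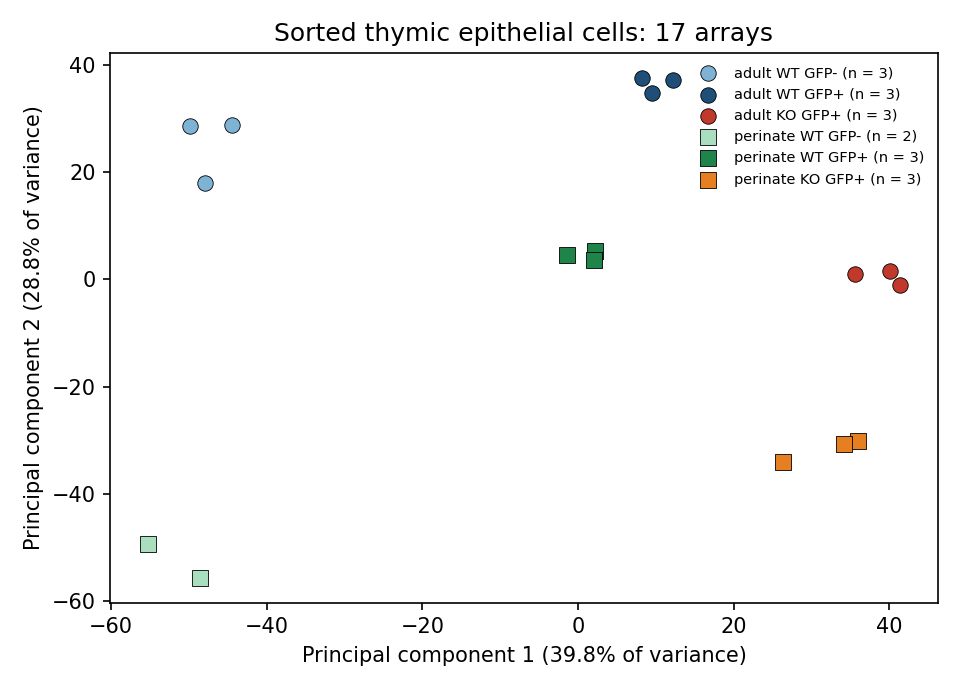
Principal components of the 13842 tested genes on the log2 scale, 1 point per array, coloured by group; both axes are component scores and the third component is not drawn. GFP- arrays lie at negative scores of the first component and KO GFP+ arrays at the positive end, and perinate arrays lie below the adult arrays of the same sort and genotype on the second.

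Transcripts of the targeted gene and of the reporter differed with the sort and passed no test between genotypes. Aire read 4354.6 to 6196 on the adult WT GFP+ arrays and 4093.9 to 5335.7 on the perinate ones, against 494.9 to 930.1 in adult GFP- cells and 270 to 351 in perinate GFP- cells. In KO GFP+ cells Aire read 4688.8 to 5241.5 in adults and 4071.7 to 6000 in perinates. The part of the gene that was deleted is not stated in the labels, so this probe set does not check the genotype. G6pc2 averaged 9141 ± 484 (SD, n = 3) in adult WT GFP+ cells, 9023 ± 103 in adult KO cells, 7559 ± 403 in perinate WT GFP+ cells and 8050 ± 550 in perinate KO cells. Neither transcript passed the test between WT and KO (Aire, adjusted p = 0.931 in adults and 0.662 in perinates). Neither passed between ages in WT GFP+ cells (Aire, log2 difference -0.09 ± 0.21 (SE), adjusted p = 0.799; G6pc2, -0.27 ± 0.14, adjusted p = 0.177).

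Adult KO and WT GFP+ cells were compared to find the transcripts that depend on Aire. Transcripts of peripheral organs fell together without Aire. The salivary mucin-like Mucl2 fell from an intensity of 4061 ± 604 to 42.99 ± 23.7, a 103-fold difference (adjusted p = 2.34e-07). Ly6g, a surface antigen of neutrophils, fell 80.3-fold from 2388 ± 273 to 29.68 ± 2.78 (adjusted p = 6.17e-14) and Ly6a2, of the same family, fell 49.4-fold. Tac2, which encodes a tachykinin precursor, fell 32.5-fold. Gpr50, a relative of the melatonin receptors, fell 31-fold, Akr1c18, a progesterone-metabolising enzyme, 29.8-fold, the casein gene Csn1s1 25.6-fold and Amtn, of enamel, 24.1-fold. In each of these genes, as in those given below as the largest changes of a comparison, the compared groups did not overlap on any array.

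The gene lists, like the comparisons, their tests and thresholds, were fixed before the data were examined, and the organ lists fell as groups in adult KO cells. Where a list is given with no second count, the count adjusted over the list alone was the same. Of 11 measured transcripts commonly cited as Aire-induced, 10 fell (11 when adjusted over the list alone; camera adjusted p = 1.84e-16). Of 20 gut and stomach transcripts 18 fell (18 adjusted over the list alone, adjusted p = 3.5e-24), among them Pgc, a gastric pepsinogen, 17.9-fold and the trefoil factor Tff3 8.74-fold. Of 19 liver transcripts 17 fell (17 adjusted over the list alone, adjusted p = 1.03e-21), led by the cytochrome Cyp1a2 at 19.5-fold, the tryptophan-degrading Tdo2 at 9.52-fold and the fibrinogen chain Fgg at 9.14-fold. Of 14 pancreas transcripts 12 fell (12 adjusted over the list alone, adjusted p = 2.16e-14), with the digestive protease precursor Ctrb1 at 10.7-fold and the hormones Sst and Ppy at 8.28-fold and 7.1-fold. Of 16 brain transcripts 9 fell (11 adjusted over the list alone, adjusted p = 2.35e-07), with neurotensin (Nts) at 16.2-fold and Pcp4, a Purkinje cell transcript, at 12-fold. The abundant synaptic Syt1 differed by 0.15 ± 0.13 on the log2 scale (adjusted p = 0.427). Of 6 milk and seminal transcripts 5 fell (5 adjusted over the list alone, adjusted p = 5.12e-07). The exception was the casein Csn2, at 5990 ± 698 in WT and 7089 ± 264 in KO cells (adjusted p = 0.338). These 6 lists kept their calls when the correlation between genes was estimated, the highest adjusted p being 0.0486 for brain.

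Smaller groups moved with them. Of 6 salivary and lacrimal transcripts 5 fell (5 adjusted over the list alone, adjusted p = 4.17e-06; adjusted p = 0.057 with an estimated correlation), including the odorant carrier Obp2a at 19.7-fold. Of 12 keratinisation transcripts 6 fell (7 adjusted over the list alone, adjusted p = 0.000107; adjusted p = 0.249 with an estimated correlation), led by Krt77 at 6.02-fold. Of 12 muscle transcripts 4 fell, led by the acetylcholine receptor subunit Chrna1, and 2 rose (5 and 2 adjusted over the list alone, adjusted p = 0.015; adjusted p = 0.108 with an estimated correlation). Of 7 testis transcripts 3 fell (4 adjusted over the list alone, adjusted p = 0.0175; adjusted p = 0.108 with an estimated correlation), and of 4 retina and lens transcripts, too few for a set test, 3 fell. The testis call was lost with quantile normalization (adjusted p = 0.0533) and without the filter on dim probe sets (adjusted p = 0.231).

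Immune signalling transcripts fell as well, whereas antigen-presentation lists passed no test. Of 10 chemokines 5 fell in adult KO cells (5 adjusted over the list alone, adjusted p = 0.000176), with the dendritic cell attractant Xcl1 at 4.81-fold, Ccl22 at 4.64-fold and Ccl5 at 3.52-fold. The call held with an estimated correlation (adjusted p = 0.0338). Of 12 interferon-response transcripts 6 fell (7 adjusted over the list alone, adjusted p = 0.000543; adjusted p = 0.266 with an estimated correlation), led by the antiviral Ifit3 at 4.46-fold and Rsad2 at 3.51-fold. Of 9 fetal growth transcripts 3 fell (4 adjusted over the list alone, adjusted p = 0.0103; adjusted p = 0.279 with an estimated correlation), led by the imprinted Dlk1 at 5.33-fold and Igf2 at 3.55-fold. Markers of dendritic cells and macrophages, cells the CD45 gate excludes, split: 6 of 9 fell, led by the macrophage receptor Adgre1 at 3.85-fold, and 2 rose, among them Fcer1g, an Fc receptor chain, at 1.56-fold. The same 6 and 2 passed when adjusted over the list alone (adjusted p = 0.0241; 0.266 with an estimated correlation and 0.0835 without the filter on dim probe sets). No costimulation transcript of 10 passed (0 adjusted over the list alone, adjusted p = 0.793), MHC class II had 2 of 13 higher (adjusted p = 0.712), class I 2 of 13 lower (adjusted p = 0.299) and medullary regulators 0 of 12 (adjusted p = 0.856). The costimulation median lay above 0 and the direction of its test below, and the regulators' median lay below 0 and their mean above. Among the regulators was Fezf2, a second regulator of ectopic expression, at 4071 ± 380 and 3666 ± 337 (adjusted p = 0.547).

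Fewer genes rose by large amounts. Ctla4, an inhibitory receptor best known from T cells, rose 7.04-fold from 159.9 ± 9.99 to 1130 ± 125 (adjusted p = 8.96e-08), the secreted neural factor Tafa1 4.36-fold, the monoamine oxidase Maoa 3.89-fold and the retinal opsin Rgr 3.68-fold. The olfactory receptor Olfr1136, the acyl-CoA thioesterase Acot12, the GABA receptor subunit Gabra4 and Ptchd4 rose 3.4-fold to 3.64-fold. Of the thymocyte markers 0 of 8 passed (adjusted p = 0.696). The fibroblast list had Lum and Dcn, matrix proteoglycans, 2.39-fold and 2.15-fold higher with 2 of its 7 members lower (3 higher and 2 lower adjusted over the list alone, adjusted p = 0.341). Of all genes, 1254 were higher and 1496 lower in adult KO cells, and of those that differed at least 2-fold 76 were higher and 606 lower. The count of higher genes was the less stable, at 631 (with 1208 lower) without adult KO array 2 and 792 to 957 without a WT array. The majority turned with array weights (2042 higher, 1825 lower) and the filter at the 60th percentile (969 and 905), and quantile normalization left 1461 and 1462.

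In perinates the same comparison was led by the same 4 transcripts. Mucl2 fell 89.5-fold, from 2980 ± 340 to 33.21 ± 2.84 (adjusted p = 4.96e-07), Ly6g 79.7-fold, Ly6a2 58.1-fold and Tac2 32.4-fold. The kallikrein Klk1b8 fell 27.7-fold (adjusted p = 1.09e-11), the retinoic acid carrier Crabp1 20.2-fold (adjusted p = 3.52e-12), and the B cell attractant Cxcl13 16.8-fold, from 2787 ± 102 to 172.9 ± 61.6 (adjusted p = 7.19e-09). Of the 11 transcripts cited as Aire-induced 10 fell (10 adjusted over the list alone, adjusted p = 9.67e-15). Of 20 gut and stomach transcripts 18 fell and 1 rose (18 and 1 adjusted over the list alone, adjusted p = 2.75e-18). Of 19 liver transcripts 17 fell and 1 rose (17 and 1 adjusted over the list alone, adjusted p = 7.92e-14). Pancreas lost 12 of 14 (12 adjusted over the list alone, adjusted p = 4.83e-13). Brain lost 10 of 16 (12 lower and 1 higher adjusted over the list alone, adjusted p = 1.26e-07) and salivary and lacrimal 5 of 6 (6 adjusted over the list alone, adjusted p = 4.23e-07). Pcp4 fell 15.8-fold, Csn1s1 15.1-fold, Ctrb1 9.89-fold, Pgc 9.48-fold, Cyp1a2 8.92-fold and the gastric mucin Muc5ac 8.47-fold. Those 6 lists also kept their calls with an estimated correlation (highest adjusted p = 0.0486, for salivary and lacrimal).

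Keratinisation and chemokine transcripts fell in perinate KO cells too, and cell cycle transcripts, not called in adult KO cells (1 of 21 higher, 0 adjusted over the list alone, adjusted p = 0.293), rose. Of 12 keratinisation transcripts 10 fell (10 adjusted over the list alone, adjusted p = 3.38e-07; adjusted p = 0.144 with an estimated correlation), with Krt77 5.63-fold and Krt1, of suprabasal skin, 3.39-fold lower. Of 10 chemokines 6 fell (6 adjusted over the list alone, adjusted p = 0.000118; adjusted p = 0.0333 with an estimated correlation), led by Ccl20, Ccl5 and Ccl17 at log2 differences of -1.50, -1.47 and -1.37. Of 21 cell cycle transcripts 12 rose (15 adjusted over the list alone, adjusted p = 0.000208; adjusted p = 0.429 with an estimated correlation), led by the mitotic checkpoint kinase Bub1b at 0.65. Bub1b lost its own call without perinate WT GFP+ array 5 or 7 (adjusted p = 0.0836 and 0.0622, at 0.50 and 0.55). Milk and seminal transcripts fell in 5 of 6 (5 adjusted over the list alone, adjusted p = 4.02e-05; adjusted p = 0.07 with an estimated correlation). Muscle transcripts fell in 6 of 12 with 1 higher (8 and 3 adjusted over the list alone, adjusted p = 0.00691; adjusted p = 0.0803 with an estimated correlation). Interferon-response transcripts fell in 5 of 12 (5 adjusted over the list alone, adjusted p = 0.0102; adjusted p = 0.429 with an estimated correlation). Of 12 tuft cell markers 4 fell, among them the channel Trpm5 at -1.16 and Avil at -0.82 (4 adjusted over the list alone, adjusted p = 0.0331; 0.525 with an estimated correlation, 0.0975 with fry, 0.209 with quantile normalization and 0.0817 without the filter on dim probe sets). Of 16 proteins reported to assist Aire 4 rose, without a call for the list (3 adjusted over the list alone, adjusted p = 0.313). Class II transcripts changed in 3 of 13, the transactivator Ciita being higher by 0.94 and H2-Ob by 0.66 (adjusted p = 0.456 for the list). Costimulation transcripts changed in 1 of 10 (adjusted p = 0.649).

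Among increases in perinate KO cells, Epyc, a cartilage proteoglycan, led at 3.83-fold, from 210.1 ± 13.5 to 837.6 ± 274 (adjusted p = 1.38e-05). Olfr1136, the adhesion molecule Chl1, the collectin Colec12 and the sodium channel Scn9a rose 2.96-fold to 3.2-fold, Kctd4 2.9-fold and the histone gene H2ac4 2.84-fold, and Maoa 2.48-fold. In all, 1863 genes were higher and 1801 lower, and 62 and 593 when at least 2-fold was required. The share of higher genes was 50.8% on the deposited scale and fell to 32.3% (1051 higher, 2202 lower) with arrays centred on their median. It was 41.4% without the filter on dim probe sets and 49.8% after quantile normalization. On perinate KO arrays 2 and 3 the Y-linked Uty, chosen with Xist after the values were seen, read 19.24 and 16.14, against 168.9 to 366.2 on the other 15 arrays, and Xist read 5203 and 5167 against 2104 to 4509. With array 1 as the only perinate KO array, assumed to vary like the other groups, a choice made after the data were seen, 1171 genes were called, 176 higher and 995 lower. Leaving out perinate KO array 2 alone gave 2400 called genes, 940 of them higher, and leaving out perinate WT GFP+ array 5 gave 2439, 987 of them higher.

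The Aire-dependent transcripts of both ages were largely the same genes. Of the 606 genes at least 2-fold lower in adult KO cells and the 593 in perinate KO cells, 457 were shared, against 26 if the lists were independent (odds ratio 296, 95% interval 230 to 381, Fisher's exact test; genes are not independent replicates). The KO effects of the ages, which share no array, correlated across genes at r = 0.801 and rho = 0.515. Of genes at least 2-fold higher, 76 and 62, 18 were shared.

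A test of whether the KO effect differed with age called 167 genes, 100 with a less negative or more positive effect in perinates and 67 the other way. Tdo2 fell from 656.2 ± 83.2 to 70.2 ± 18.4 in adults and from 201.2 ± 69.6 to 96.99 ± 14.6 in perinates (adjusted p of the difference 0.00462). Akr1c18 fell from 1264 to 41.97 in adults and from 562.4 to 57.25 in perinates (adjusted p = 0.022). The developmental regulator Irx4 went from 280.7 to 140 in adults and from 144.5 to 309.7 in perinates (adjusted p = 0.00542), and the cytochrome Cyp2j13 from 133 to 83.28 and from 53.89 to 144.4 (adjusted p = 0.000238). In the other direction, Ctla4 rose to 1130 in adults but to 156.6 from 74.45 in perinates (adjusted p = 0.022). Acot12 rose to 516.1 from 148.4 but to 124.1 from 103 (adjusted p = 0.00231), and Rgr to 260.4 from 70.01 but 72.92 from 65.02 (adjusted p = 0.00723). The clock repressor Nr1d1 read 688.3 and 934.9 in adult WT and KO cells and 853.4 and 279.8 in perinates (adjusted p = 0.0286). Cyp17a1, of androgen synthesis, read 450.1 and 438 in adults and 304.9 and 74.73 in perinates (adjusted p = 0.00462). Cxcl13 fell to 492.1 from 2514 in adults and to 172.9 from 2787 in perinates (adjusted p = 0.0446). Several of these calls lay close to the threshold and were lost in fits with 1 array fewer, in which the log2 differences stayed about as large. Akr1c18 lost its call without adult WT GFP+ array 8, adult KO array 2, perinate WT GFP+ array 5 or perinate KO array 3 (adjusted p = 0.054 to 0.0624, log2 difference 1.40 to 1.59 against 1.62 with all arrays). Ctla4 lost its call without adult WT GFP+ array 8, adult KO array 2 or perinate WT GFP+ array 5 (0.0552 to 0.067, and -1.69 to -1.49 against -1.71). Nr1d1 lost its call without adult WT GFP+ array 7 or 8, adult KO array 1 or 2, perinate WT GFP+ array 5 or perinate KO array 2 or 3 (0.0583 to 0.075, and -2.11 to -1.86 against -2.08). Cxcl13 lost its call without any 1 of the 12 arrays except adult KO array 3 and perinate KO array 1 (0.0563 to 0.108, and -1.69 to -1.49 against -1.66).

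By list, the KO loss was smaller in perinates for liver, with 3 of 19 passing (8 adjusted over the list alone). Adjusted p was 8.42e-08, and 0.0486 with an estimated correlation. Liver averaged 8.007 and 7.351 (log2) in adult and perinate WT but 6.268 and 6.211 in KO GFP+ cells. Gut and stomach lost less too, with 6 of 20 (8 and 1 the other way adjusted over the list alone). Adjusted p was 0.00251, and 0.178 with an estimated correlation. Fibroblast markers had 2 of 7 below, among them Col1a1, which fell from 397 to 173.8 in perinates and from 285.1 to 215.3 in adults (4 adjusted over the list alone, adjusted p = 0.000139; adjusted p = 0.165 with an estimated correlation). The share of the 167 genes above 0 was 59.9%, and 34.9% (76 and 142) with arrays centred on their median. Leaving out 1 array lowered the count to 86, 73 or 52 for adult WT GFP+ arrays 6, 7 or 8, to 95, 62 or 101 for adult KO arrays 1, 2 or 3. It fell to 58 for perinate WT GFP+ array 5 and to 82 or 60 for perinate KO arrays 2 or 3.

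**Figure D2:**
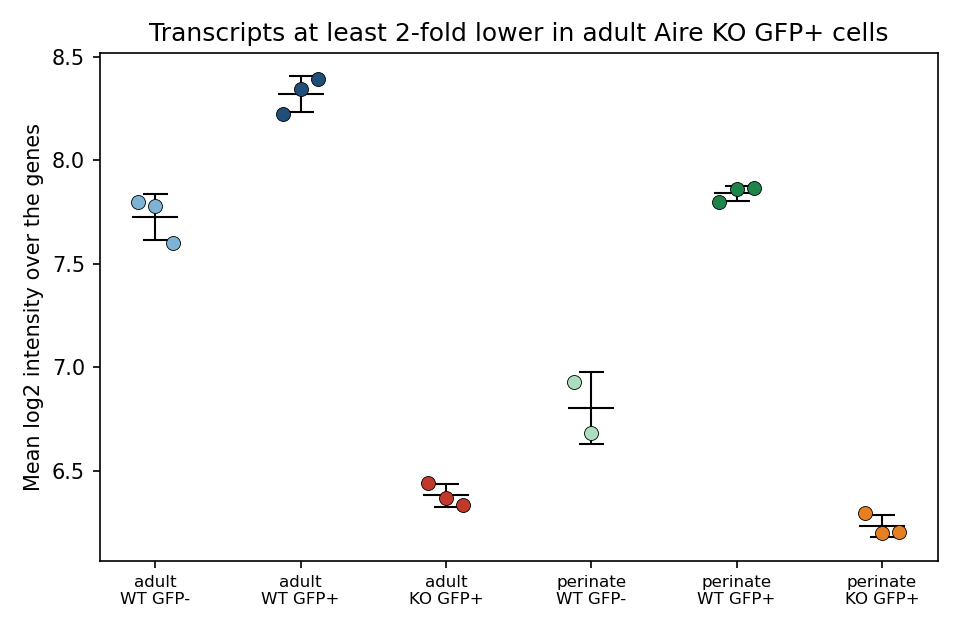
Mean log2 intensity of the 606 transcripts that fell at least 2-fold without Aire in adults, 1 point per array and a bar at each group mean, for the 6 groups. The adult WT GFP+ arrays lie between 8.22 and 8.39, the perinate WT GFP+ arrays between 7.80 and 7.86, and all 6 KO arrays between 6.20 and 6.44.

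Perinate and adult WT GFP+ cells were compared to learn whether Aire-expressing cells differ with age. Perinate cells had less of many peripheral-organ transcripts and more of growth-related ones. Anxa10, a gastric annexin, was 11.8-fold lower in perinates, at 136.4 ± 36.3 against 1578 ± 124 (adjusted p = 1.14e-07), and Fabp9, a testis fatty acid carrier, 7.23-fold lower, at 430.3 ± 254 against 2609 ± 322 (adjusted p = 0.000275). The secretoglobin Scgb2b27 was 7.13-fold lower, the interferon-inducible Ifi205 7.12-fold, the hyaluronan-binding Tnfaip6 5.39-fold, the neuroendocrine Resp18 4.98-fold, the heat-shock protein Hsph1 4.53-fold and the retinol acyltransferase Lrat 4.46-fold. Stmn2, a neuronal microtubule regulator, was 4.92-fold higher in perinates, at 441.8 ± 162 against 86.31 ± 6.27 (adjusted p = 8.47e-06), the adhesion protein Mpzl2 4.13-fold, the matrix protein Efemp1 3.8-fold, the cytokine receptor Lifr 3.51-fold and Olfr920 3.39-fold. The proteoglycan Vcan was 3.33-fold higher, the peptidase Mme 3.23-fold and Tox3 3.05-fold.

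Organ lists were lower in perinate WT GFP+ cells. Of 19 liver transcripts 14 were lower (16 adjusted over the list alone, camera adjusted p = 9.46e-08), with Tdo2 at 3.38-fold, the apolipoprotein Apoc3 at 2.96-fold and Cyp1a2 at 2.32-fold. This call alone held with an estimated correlation (adjusted p = 0.0486). Of 20 gut and stomach transcripts 11 were lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 7.1e-06; adjusted p = 0.0637 with an estimated correlation), led by the brush-border Sis, Vil1 and Fabp2 at log2 differences of -1.62, -1.25 and -1.24. Of 7 transcripts tied to Fezf2 6 were lower (6 adjusted over the list alone, adjusted p = 9.14e-05; adjusted p = 0.057 with an estimated correlation), among them Ttr at -1.01 and Fezf2 itself at -0.58 ± 0.16. Fezf2 lost its call without adult array 7 or 8 or perinate array 5 (adjusted p = 0.0553, 0.0568 and 0.0749, at -0.54 to -0.44). Of the 11 examples of Aire-induced transcripts 5 were lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.018; adjusted p = 0.168 with an estimated correlation). Brain transcripts were lower in 7 of 16 (8, with 1 higher, adjusted over the list alone, adjusted p = 0.00477; adjusted p = 0.2 with an estimated correlation), led by Resp18. Pancreas transcripts were lower in 6 of 14 (6, with 1 higher, adjusted over the list alone, adjusted p = 0.0133), led by glucagon (Gcg) at -0.97. The call was lost with an estimated correlation (adjusted p = 0.178) and without the filter on dim probe sets (adjusted p = 0.106). Milk and seminal transcripts were lower in 4 of 6 (4 adjusted over the list alone, adjusted p = 0.00135; adjusted p = 0.143 with an estimated correlation). Keratinisation had 1 of 12 lower (adjusted p = 0.843) and muscle 4 lower and 2 higher of 12 (adjusted p = 0.862, its median above 0 and its mean below). Testis had 2 each way of 7 (adjusted p = 0.734) and salivary and lacrimal 2 lower and 1 higher of 6 (adjusted p = 0.268).

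Transcripts of the presentation and recruitment of T cells were also lower in perinates. Of 13 class I transcripts 5 were lower (6 adjusted over the list alone, adjusted p = 0.00296; adjusted p = 0.186 with an estimated correlation), led by the immunoproteasome subunits Psmb8 and Psmb9 at -0.81 and -0.74. B2m differed by -0.04 (adjusted p = 0.781). Of 10 chemokines 4 were lower (6 adjusted over the list alone, adjusted p = 0.0117; adjusted p = 0.0961 with an estimated correlation), led by Ccl20, Ccl17 and Xcl1 at -1.21 to -0.97. Ccl20 lost its call without adult array 8 or perinate array 5 or 7 (adjusted p = 0.0508, 0.0562 and 0.063, at -1.17 to -1.06). Of 10 costimulation transcripts 3 were lower (6 adjusted over the list alone, adjusted p = 0.0158; adjusted p = 0.138 with an estimated correlation), the ligand Cd70 at -0.86, the receptor Tnfrsf9 at -0.73 and Pdcd1lg2 at -0.71. The class II list held changes both ways, with the peptide-loading modulator H2-Ob at -1.14, and was not called (4 lower and 2 higher of 13, 5 and 2 adjusted over the list alone, adjusted p = 0.438). Markers of dendritic cells and macrophages were lower in 4 of 9 (5 adjusted over the list alone, adjusted p = 0.00592; adjusted p = 0.179 with an estimated correlation), with Cd209a at -0.86, Adgre1 at -0.75 and the lysozyme Lyz2 at -0.65.

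Growth and mesenchymal transcripts were higher in perinates. Of 21 cell cycle transcripts 5 were higher (6 adjusted over the list alone, adjusted p = 0.000176; adjusted p = 0.429 with an estimated correlation), led by the cyclin Ccnb2 and the nucleotide reductase Rrm2 at 0.67 and 0.65. Ccnb2 lost its call without adult array 6 or perinate array 7 (adjusted p = 0.0537 and 0.0771, at 0.64 and 0.56). The fetal growth list had 3 of 9 higher (3 adjusted over the list alone, adjusted p = 0.00826), the imprinted Peg3 at 1.56 ± 0.13 and Mest at 0.84 and the RNA-binding Igf2bp3 at 0.82. It lost its call with an estimated correlation (adjusted p = 0.266) and without the filter on dim probe sets (adjusted p = 0.0645). Fibroblast markers had 4 of 7 higher (5, with 1 lower, adjusted over the list alone, adjusted p = 0.00383; adjusted p = 0.266 with an estimated correlation), led by Lum at 1.11 and Dcn at 1.04. No endothelial marker of 5, thymocyte marker of 8, B cell marker of 4 or retina and lens transcript of 4 passed, and of 3 erythroid transcripts 1 was higher and 1 lower. In total 1179 genes were higher and 1888 lower in perinates, and 81 and 301 at 2-fold or more. The share higher was 38.4% on the deposited scale, 56.9% (2012 higher, 1522 lower) with arrays centred on their median and 49.4% (1747 and 1791) after quantile normalization.

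The 606 transcripts that fell at least 2-fold without Aire in adults had a median log2 age difference of -0.46 in WT GFP+ cells, with 283 called lower in perinates and 10 higher. Because adult arrays enter both the choice of these genes and the age difference, the choice was repeated in perinates. The 593 genes chosen there had a median of -0.282 (211 lower, 32 higher). In KO GFP+ cells medians were -0.082 for the 606 (90 and 36) and -0.141 for the 593 (122 and 17). Genes called in neither KO comparison had a median age difference of 0.032 in WT cells. With arrays centred on their median the -0.46 became -0.384.

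**Figure D3:**
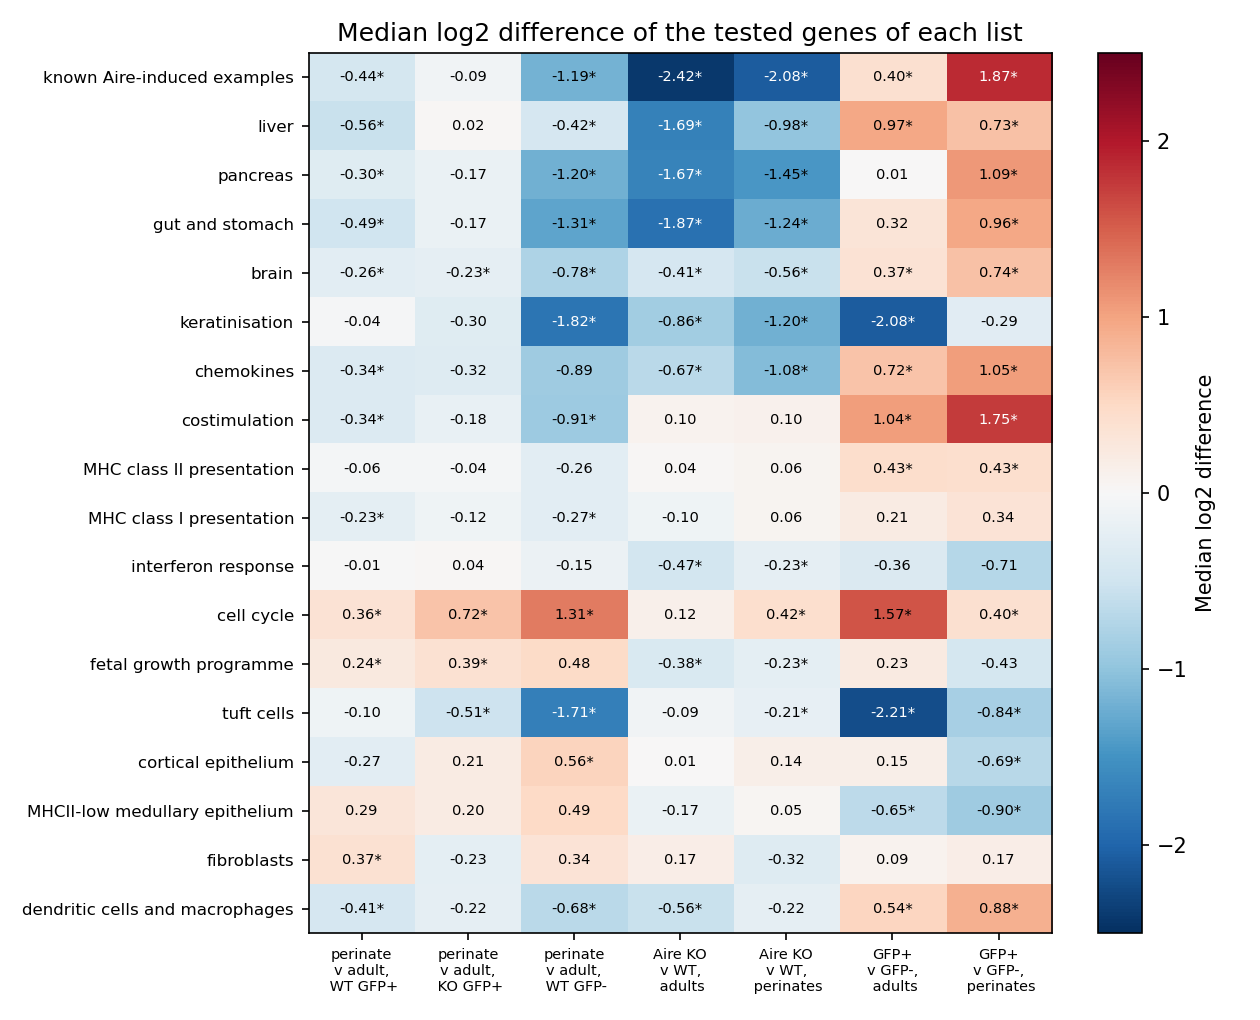
Median log2 difference of fixed gene lists with at least 5 tested genes (vertical axis) by comparison (horizontal axis), as a colour scale. An asterisk marks a camera adjusted p under 0.05. In both Aire-knockout comparisons the liver, gut and stomach, pancreas and brain lists lie below 0 with an asterisk. The tuft cell list lies below 0 and the cell cycle list above 0, with asterisks, in both comparisons of GFP+ with GFP- cells.

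Perinate and adult KO GFP+ cells, compared to see which age differences remain without Aire, also differed in growth transcripts and in single immune genes. Ifi205 was 14.5-fold lower in perinates, at 142.9 against 2068 (adjusted p = 2.83e-06), Ctla4 7.19-fold, the thyroxine carrier Serpina7 6.84-fold and Tnfaip6 6.34-fold. Stmn2 was 7.76-fold higher, at 869.1 against 113.7 (adjusted p = 3.6e-07), Vcan 5.91-fold and the aldehyde dehydrogenase Aldh1a7 4.32-fold. Of 21 cell cycle transcripts 17 were higher in perinates (18 adjusted over the list alone, adjusted p = 5.34e-09; adjusted p = 0.209 with an estimated correlation), led by the helicase subunit Mcm5 at 0.90. The fetal growth list had 3 of 9 higher, led by Peg3 at 1.63 and Mest at 1.43 (4 adjusted over the list alone, adjusted p = 0.00431; adjusted p = 0.235 with an estimated correlation). Brain transcripts were called lower (adjusted p = 0.00625, and 0.211 with an estimated correlation), as were those tied to Fezf2 (0.00745 and 0.158). Liver was not (2 lower and 1 higher of 19, 2 and 0 adjusted over the list alone, adjusted p = 0.851). Its median lay above 0 and its mean below. Nor were gut and stomach (5 lower and 1 higher of 20, 0.111), pancreas (0.124) and the Aire-induced examples (0.363). No immune list was called either. Lower were 4 of 10 chemokines (adjusted p = 0.115), 3 of 10 costimulation transcripts (0.229) and 1 of 13 class I transcripts (0.21). The age effects of WT and KO cells correlated across genes at r = 0.654, with 928 genes lower in both against 239 for independent lists and 648 higher in both against 158. In all, 1850 genes were higher and 1751 lower. The majority turned without adult KO array 3 (1120 and 1443), without perinate KO array 2 (1369 and 1410) or 3 (1336 and 1398), with arrays centred on their median (1786 and 1905) and without the filter on dim probe sets (1796 and 1835). The Y-linked Uty, 7.3-fold lower in perinate KO cells, was low on arrays 2 and 3 alone, and with array 1 as the only perinate KO array 1876 genes were called, 828 of them higher.

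GFP+ and GFP- cells of WT adults were compared to describe what accompanies the Aire reporter within MHC class II-high cells. Markers of tuft cells, the chemosensory cells of epithelia, were higher in GFP- cells. Rgs13, a regulator of G-protein signalling, read 2017 ± 239 in GFP- and 66.21 ± 30.4 in GFP+ cells, a 32.3-fold difference (adjusted p = 2.08e-06). The taste transducin Gnat3 was 21.7-fold lower in GFP+ cells, the phospholipase Plcb2 17.6-fold and Trpm5 16.3-fold. Mctp1 and the kinase Bmx were 16.6-fold and 15.7-fold lower, the bitter receptor Tas2r108 13.5-fold and the keratinocyte protein Krtdap 11.2-fold. All 12 tuft cell markers were lower in GFP+ cells (12 adjusted over the list alone, adjusted p = 1.64e-12; adjusted p = 0.0637 with an estimated correlation). So were 9 of 12 keratinisation transcripts (9 adjusted over the list alone, adjusted p = 5.34e-06; adjusted p = 0.178 with an estimated correlation) and 5 of 8 markers of MHCII-low medullary epithelium (adjusted p = 0.0264; adjusted p = 0.266 with an estimated correlation).

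Adult GFP+ cells were higher in proliferation and costimulation transcripts. All 21 cell cycle transcripts were higher (21 adjusted over the list alone, adjusted p = 3.75e-12; adjusted p = 0.157 with an estimated correlation), led by the cyclin Ccna2 at 4.41-fold. Of 10 costimulation transcripts 9 were higher (9 adjusted over the list alone, adjusted p = 0.000103; adjusted p = 0.0463 with an estimated correlation), led by Cd40 at 4.02-fold, from 811.2 to 3252, with Tnfrsf9 and Icosl at log2 differences of 1.86 and 1.68. Class II transcripts were higher in 8 of 13 (8 adjusted over the list alone, adjusted p = 0.00629; adjusted p = 0.154 with an estimated correlation), led by Ciita at 1.48, while Cd74 differed by 0.04. Chemokines were higher in 6 of 10 with 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0241; adjusted p = 0.127 with an estimated correlation), led by Xcl1 at 1.87. Of the medullary regulators 7 of 12 were higher and 1 lower (adjusted p = 0.0331; 0.365 with an estimated correlation and 0.085 with quantile normalization), among them Aire at 7.55-fold and Irf4 at 1.08. The largest increases were in Olfr1136 at 12-fold, the claudin Cldn13 at 11.1-fold, Tvp23a at 10.4-fold, the methyltransferase cofactor Dnmt3l at 9.89-fold, the kynurenine enzyme Kmo at 9.08-fold, Reg4 at 8.96-fold, Tdo2 at 7.94-fold and the stress-hormone binder Crhbp at 7.57-fold. G6pc2 was 5.67-fold higher. The sort itself sets it and Aire, in the pancreas and regulator lists. Liver was called (14 higher and 2 lower of 19, adjusted p = 4.22e-05; adjusted p = 0.107 with an estimated correlation), as were milk and seminal (5 higher and 1 lower of 6, adjusted p = 0.0112; adjusted p = 0.211 with an estimated correlation), the Aire-induced examples (5 of 11 higher, adjusted p = 0.0219), brain (9 higher and 2 lower of 16, adjusted p = 0.0326) and muscle (5 of 12 higher, adjusted p = 0.0388). The last 3 lost their calls with an estimated correlation (adjusted p = 0.178, 0.344 and 0.163). Pancreas (5 higher and 2 lower of 14, adjusted p = 0.464) and gut and stomach (9 higher and 4 lower of 20, 10 and 4 adjusted over the list alone, adjusted p = 0.124) were not called. Markers of dendritic cells and macrophages were higher in 6 of 9 (adjusted p = 0.00826; adjusted p = 0.188 with an estimated correlation), led by Adgre1 at 2.25, and thymocyte markers had 1 each way of 8 (adjusted p = 0.947). In all, 3422 genes were higher and 2788 lower in GFP+ cells (3173 and 3295 after quantile normalization).

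In perinates, with 2 GFP- arrays, GFP+ cells were higher in organ and costimulation transcripts. The cartilage protein Ucma was 24.3-fold higher (adjusted p = 8.35e-11), G6pc2 22.9-fold, the kynureninase Kynu 22.4-fold, Cxcl13 21.8-fold, Serpinb12 19.3-fold, Lyz2 16.7-fold, from 197.7 to 3314 ± 379 (adjusted p = 4.22e-13), Tvp23a 15.8-fold and Aire 15.4-fold. Higher in GFP- cells were Gnat3 at 15.5-fold, the desmosomal cadherin Dsc3 at 11.5-fold, the amino acid transporter Slc38a4 at 9.71-fold, the glycine receptor subunit Glrb at 9.36-fold, the cadherin Fat3 at 9.13-fold and the stromal chemokine Cxcl12 at 8.29-fold, at 747.1 against 90.19. Of 10 costimulation transcripts 9 were higher in GFP+ cells (9 adjusted over the list alone, adjusted p = 7.1e-06; adjusted p = 0.028 with an estimated correlation), with Cd80 at 7.01-fold, Cd86 at 5.84-fold and Cd40 at 4.56-fold. The Aire-induced examples were higher in 9 of 11 (10 adjusted over the list alone, adjusted p = 4.47e-06; adjusted p = 0.0333 with an estimated correlation). Pancreas transcripts were higher in 12 of 14 (12 adjusted over the list alone, adjusted p = 3.48e-05; adjusted p = 0.0486 with an estimated correlation). Liver was higher in 16 of 19, gut and stomach in 16 of 20 and brain in 12 of 16 (adjusted p = 3.04e-06, 3.48e-06 and 4.79e-06; adjusted p = 0.07, 0.057 and 0.0637 with an estimated correlation).

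Tuft cell markers were lower in 8 of 12 in perinate GFP+ cells (adjusted p = 0.000788; adjusted p = 0.332 with an estimated correlation). Cell cycle transcripts were higher in 10 of 21 (adjusted p = 0.016; adjusted p = 0.587 with an estimated correlation). Markers of cortical epithelium, cells that the Ly51 gate excludes, were lower in 7 of 11 and higher in 2 (7 and 3 adjusted over the list alone, adjusted p = 0.0279; adjusted p = 0.163 with an estimated correlation), among them Cxcl12 and the thymic serine protease Prss16 at 4.91-fold. Of the medullary regulators 8 of 12 were higher and 1 lower (adjusted p = 0.00477; adjusted p = 0.211 with an estimated correlation), with Irf4 at 7.35-fold and Fezf2 at 5.83-fold. Markers of other cell types were higher in GFP+ cells beside the costimulation transcripts: myeloid in 7 of 9 (adjusted p = 0.000208; adjusted p = 0.0961 with an estimated correlation), and, too few for a set test, B cell in 3 of 4 and erythroid in 3 of 3. Dissociation-stress transcripts were lower in 4 of 13, among them the immediate-early Ier3 (adjusted p = 0.0292; adjusted p = 0.492 with an estimated correlation). On perinate GFP- array 1 the salivary secretion gene Bpifa2, chosen like Car6 after the values were seen, read 10680, against 71.72 on array 2 and at most 461.9 on the other 15 arrays, and the carbonic anhydrase Car6 read 799.8 against 52.76. In all 3176 genes were higher and 2839 lower in GFP+ cells. The majority depended on the GFP- array, with 3005 higher and 2060 lower without array 1 but 2385 and 2659 without array 2, and quantile normalization left 3140 and 3168.

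Whether the GFP contrast differed with age was tested directly, and 2761 genes were called, 1478 with a higher and 1283 with a lower GFP+ to GFP- ratio in perinates. Here too the majority turned in some fits, with 1528 and 886 without perinate GFP- array 1 but 1037 and 1317 without array 2, 1424 and 1441 without perinate GFP+ array 6 and 1657 and 1704 with every probe set on its own. All 12 tuft cell markers had a higher ratio in perinates (12 adjusted over the list alone, adjusted p = 7.66e-10; adjusted p = 0.0961 with an estimated correlation). Trpm5 fell from 1907 in GFP- to 115.9 in GFP+ cells of adults and from 304.8 to 133.7 in perinates (adjusted p = 1.73e-05). Keratinisation had 8 of 12 in that direction (9, with 1 the other way, adjusted over the list alone, adjusted p = 7.1e-06; adjusted p = 0.184 with an estimated correlation), led by Lypd3 at 2150 and 281.4 in adults and 569 and 435.8 in perinates. Lyz2 read 4367 and 5193 in GFP- and GFP+ cells of adults but 197.7 and 3314 in perinates (adjusted p = 1.42e-10). The eosinophil attractant Ccl11 read 3540 and 418.7 but 211 and 349.3, the cytokine receptor subunit Il12rb2 891.7 and 400.7 but 87.19 and 423.9, and Lyz1 5746 and 6122 but 413.6 and 3731. Cd80 read 2336 and 3620 in adults and 527.7 and 3562 in perinates (adjusted p = 1.71e-05) and Fezf2 3073 and 4071 against 467.4 and 2764 (adjusted p = 1.41e-05). G6pc2 read 1614 and 9141 against 341.5 and 7559 (adjusted p = 1e-05), and Aire 690 and 5097 against 310.5 and 4773 (adjusted p = 0.0255). The Aire difference lost its call without adult GFP- array 7, perinate GFP- array 1, adult GFP+ array 6 or 8 or perinate GFP+ array 7 (adjusted p = 0.0543 to 0.119, log2 difference 0.79 to 0.99 against 1.03).

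In the other direction, 18 of 21 cell cycle transcripts had a lower ratio in perinates (19 adjusted over the list alone, adjusted p = 7.66e-10; adjusted p = 0.186 with an estimated correlation). Ccna2 read 318.8 and 1372 in adults and 1227 and 1799 in perinates. Cortical epithelial markers did so in 6 of 11 (7, with 1 the other way, adjusted over the list alone, adjusted p = 3.73e-05; adjusted p = 0.0338 with an estimated correlation). Cxcl12 read 101.6 and 82.23 in adults but 747.1 and 90.19 in perinates (adjusted p = 8.68e-08), Prss16 455.4 and 437.8 but 3192 and 732.2 (adjusted p = 0.00398), and the thymoproteasome subunit Psmb11 93.26 and 101.4 but 348.1 and 111 (adjusted p = 2.95e-06). The largest such differences were in Ptprz1, a receptor phosphatase, at 183.3 and 312.5 but 2182 and 363.6 (adjusted p = 4.37e-07), and the quinone reductase Nqo1 at 266.7 and 499.3 but 1170 and 251.8 (adjusted p = 6.98e-07). Scgb2b27 ranked between them only through perinate GFP- array 1, its log2 difference of -3.32 becoming -1.19 without that array. Its call ended without adult GFP+ array 8 (adjusted p = 0.0509) or with only the compared groups fitted (adjusted p = 0.0612). The ratio was higher in perinates for the Aire-induced examples (7 of 11, 8 adjusted over the list alone, adjusted p = 0.000173; adjusted p = 0.0516 with an estimated correlation) and pancreas (8 of 14, 9 with 1 the other way adjusted over the list alone, adjusted p = 9.15e-05; adjusted p = 0.057 with an estimated correlation). It was also higher for gut and stomach (10, with 1 the other way, of 20, 13 and 1 adjusted over the list alone, adjusted p = 9.15e-05; adjusted p = 0.0982 with an estimated correlation) and brain (8 of 16, 10 adjusted over the list alone, adjusted p = 0.000543; adjusted p = 0.144 with an estimated correlation). Liver was not called (5 and 1 the other way of 19, adjusted p = 0.507). Medullary regulators had 5 of 12 above (adjusted p = 0.0571, and 0.0362 with the adult replicate number as a block).

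Between perinate and adult GFP- cells 3065 genes were higher and 3347 lower in perinates (2269 and 3122 without perinate GFP- array 1, 2784 and 2543 without array 2, 3534 and 3091 with arrays centred on their median). Fabp9 was 34.7-fold lower in perinates, at 91.62 ± 49 against 2964 ± 447 (adjusted p = 3.23e-07), Lyz2 22-fold, the diamine oxidase Aoc1 21-fold, Ccl11 16.2-fold, Adgrg7 15.4-fold and the deiodinase Dio1 14.9-fold. Higher in perinates were Slc38a4 at 13-fold, Ptprz1 at 12.1-fold, Glrb at 11.9-fold, Susd4 at 9.23-fold, Peg3 at 8.25-fold and Cxcl12 at 7.35-fold. Of 21 cell cycle transcripts 19 were higher (adjusted p = 1.51e-10; adjusted p = 0.178 with an estimated correlation). Of 12 tuft cell markers 11 were lower (12 adjusted over the list alone, adjusted p = 4.23e-07; adjusted p = 0.157 with an estimated correlation). Gut and stomach had 17 of 20 lower and 1 higher (adjusted p = 1.6e-07; adjusted p = 0.0471 with an estimated correlation) and pancreas 12 of 14 lower (adjusted p = 7.1e-06; adjusted p = 0.047 with an estimated correlation). The Aire-induced examples had 9 of 11 lower (10 adjusted over the list alone, adjusted p = 4.84e-05; adjusted p = 0.047 with an estimated correlation). Of 7 transcripts tied to Fezf2 6 were lower (adjusted p = 7.74e-05; adjusted p = 0.057 with an estimated correlation), with Fezf2 itself 6.57-fold lower. Aire was 2.17-fold lower (adjusted p = 0.00077) and G6pc2 4.88-fold lower (adjusted p = 1.18e-08) in perinate GFP- cells. Cortical epithelial markers were higher in 6 of 11 and lower in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0146; adjusted p = 0.13 with an estimated correlation), with Prss16 at 7.03-fold and Psmb11 at 3.72-fold. Costimulation transcripts were lower in 7 of 10 (adjusted p = 0.0028; adjusted p = 0.0756 with an estimated correlation), led by Cd80 at a log2 difference of -2.19. Of the 606 transcripts that fell without Aire in adults, 397 were lower and 28 higher in perinate GFP- cells, with a median log2 difference of -0.773.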

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

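Of the tests below, those of gene choice on shared arrays, of the intensity distribution of the KO arrays, of Aire-induced genes near background without Aire, of the share of males and of splits with the common age difference removed were chosen only after the results they bear on were seen. Aire-induced transcripts were lower in perinate than in adult WT GFP+ cells, with a median log2 difference of -0.46 over 606 genes. The tables argue against a choice of genes on arrays that the age comparison shares, since genes chosen in perinates still had a median of -0.282 where 50 simulations without an age effect gave 0.002 to 0.046 (and -0.036 to 0 for genes chosen in adults). An admixture of GFP- cells in the perinate sort is argued against as sole cause at the shares estimated. Of these, 8.65% (upper bound, 147 markers) predicts -0.081 and 18% (G6pc2) -0.175. Larger shares stay open. In 27 genes well above background on all KO arrays medians were -0.007 in KO and -0.194 in WT (SDs between arrays 0.124 and 0.0491). That choice favours genes steady in KO cells, so an age difference that needs no Aire was not excluded. In the other 579 genes, with medians of -0.086 and -0.461, it cannot be told apart from an age difference in Aire's own effect, because only 11.4% of them lay above the 60th percentile on at least 1 KO array, and a biological change with age stays open and untested.

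Many genes changed by less than 2-fold in KO cells, 2068 in adults and 3009 in perinates, beside the large losses. A wider spread of intensities on KO arrays, whose mean interquartile range was 2.895 and 2.985 against 2.758 and 2.654 on WT GFP+ arrays of adults and perinates (log2), is argued against in adults, where 86.5% of these calls stayed in the same direction after quantile normalization. In perinates 65.8% stayed, between the bounds set for the test, so the spread cannot be told apart from an effect of genotype there. DNA of another strain around Aire is argued against for most of these calls, as at most 1.13% lie in the 200 tested genes nearest Aire. A sorting or hybridisation batch shared by the KO arrays cannot be told apart from a wide effect of Aire loss, because both would give the rank correlation of 0.427 between the ages over 12974 genes, and the labels name no batch.

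Y-linked transcripts were near background on perinate KO arrays 2 and 3. Uty read 19.24 and 16.14 there against 168.9 to 366.2 on the other 15 arrays, Eif2s3y 18.68 and 15.74 against 255.4 to 545.3, and Kdm5d 43.93 and 37.32 against 89.79 to 161.6. A smaller share of male mice in those 2 samples may account for this, since on 2 of the 2 arrays Xist, at 5203 and 5167, lay above every other array (2104 to 4509). No biological explanation was tested.

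The KO effect differed between the ages by a test of the difference itself in 167 genes. Over 100 drawn reassignments of age within genotype, of 200 possible, 11 gave at least as many genes, the real one included, and the highest of the others gave 1418. All 10 others moved 2 more perinates in 1 genotype than in the other, so the age difference itself enters them, and these splits decide nothing about chance. With the age difference common to both genotypes subtracted first, 1 of the same 100 splits, the real one, gave as many genes. The highest other gave 29. That step favours the real split, whose count it cannot change, so chance is not excluded. For the comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. In each only the real split gave as many genes. The real and the highest other counts were 3067 and 0 for age in WT GFP+ cells, 2750 and 1 for KO in adults and 3664 and 0 for KO in perinates. They were 6210 and 0 for GFP+ against GFP- in adults and 3601 and 0 for age in KO cells.

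Among genes, the KO effect was less negative or more positive in perinates by a log2 difference of 2.25 for Tdo2, 2.17 for Irx4, 2.11 for Cyp2j13 and 1.62 for Akr1c18. It lay below the adult effect by -2.08 for Nr1d1, -1.95 for Cyp17a1, -1.76 for Rgr, -1.71 for Ctla4, -1.66 for Cxcl13, -1.53 for Acot12 and -0.78 for Col1a1. Fits with 1 array fewer lost the calls of Akr1c18, Ctla4, Nr1d1 and Cxcl13, which lay close to the threshold, at log2 differences about as large (1.40 to 1.59, -1.69 to -1.49, -2.11 to -1.86 and -1.69 to -1.49). Cxcl13 lost its call without any of 10 arrays, with an adjusted p of at most 0.108. By list the KO effect was higher in perinates for liver (camera adjusted p = 8.42e-08) and gut and stomach (0.00251). So it was for milk and seminal (0.0302), cell cycle (0.0028) and cortical epithelium (0.0445). It was lower for fibroblasts (0.000139) and tuft cells (0.0326). Of these only liver was called with an estimated correlation (0.0486). No milk and seminal transcript of 6 (1 adjusted over the list alone) and no cell cycle transcript of 21 passed alone, and their adjusted p rose to 0.055 and 0.19 with fry and to 0.282 and 0.519 with an estimated correlation. Of 11 cortical transcripts 2 passed (adjusted p = 0.186 with an estimated correlation). Of 12 tuft cell markers 1 passed (2 adjusted over the list alone), and the call ended with fry (adjusted p = 0.276), with quantile normalization (0.167), without the filter on dim probe sets (0.0906) and with an estimated correlation (0.525).

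The difference between GFP+ and GFP- cells differed between the ages in 2761 genes. The log2 difference was higher in perinates by 3.81 for Lyz2, 3.77 for Ccl11, 3.42 for Il12rb2, 3.08 for Lyz1, 2.92 for Trpm5, 2.63 for Lypd3, 2.16 for Cd80, 2.14 for Fezf2, 2.01 for G6pc2 and 1.03 for Aire. It was lower by -3.37 for Ptprz1, -3.32 for Scgb2b27 (-1.19 without perinate GFP- array 1), -3.18 for Nqo1, -2.75 for Cxcl12, -2.19 for Prss16, -1.76 for Psmb11 and -1.61 for Ccna2. The call of Aire was lost without perinate GFP- array 1, among others (0.84, adjusted p = 0.119), and that of Scgb2b27 without adult GFP+ array 8 (-3.08, adjusted p = 0.0509). Lists higher in perinates were tuft cells (adjusted p = 7.66e-10), keratinisation (7.1e-06), pancreas and gut and stomach (both 9.15e-05), the Aire-induced examples (0.000173), brain (0.000543), Fezf2 and associated transcripts (0.00157), milk and seminal (0.0241) and costimulation (0.0413). Lower were cell cycle (7.66e-10) and cortical epithelium (3.73e-05), and cortical epithelium alone was called with an estimated correlation (adjusted p = 0.0338). Of 7 Fezf2-associated transcripts 4 passed (adjusted p = 0.108 with an estimated correlation). Of 6 milk and seminal transcripts 3 passed (4 adjusted over the list alone), with adjusted p = 0.266 with an estimated correlation and 0.182 without the filter on dim probe sets. Of 10 costimulation transcripts 2 passed, with adjusted p = 0.186 with an estimated correlation and 0.0508 with arrays centred on their median.

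Probe sets that entered no comparison of genes also fell without Aire. Of 2098 with no gene listed, 1229 were bright enough to test, and 38 were at least 2-fold lower in KO cells of both ages (53 in adults, 52 in perinates), against 3 and 6 at least 2-fold higher. Of 1399 with several genes listed, 875 were tested and 27 were at least 2-fold lower at both ages (54 and 28), against 2 and 6 higher.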

How the results depend on the processing

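The results with perinate KO array 1 alone, quantile normalization of the age difference of Aire-induced genes and the replicate block in list tests were chosen after the data were seen. No called list or named gene reversed, though each was run under only some alternatives. Counts of called genes stayed within 1.5 times under the other filters, scalings, moderation and probe set choices, with these exceptions. Requiring a 2-fold change left 382 genes for age in WT GFP+ cells, 682 for KO in adults, 655 for KO in perinates, 75 for the difference of KO effects, 1373 and 1818 for GFP+ against GFP- in adults and perinates, 1120 for the difference of those, 1899 for age in GFP- cells and 447 for age in KO cells, by construction. The filter at the 60th percentile, with fewer genes tested (9965), left 2129 for KO in perinates and 86 for the difference of KO effects. That difference had 812 genes with array weights and 252 with only the compared groups fitted; the cause was not tested. With perinate KO array 1 alone, fewer samples left 1171 genes for KO in perinates, 45 for the difference of KO effects and 1876 for age in KO cells. The overlap of Aire-dependent genes went from 457 to 1112 with no fold threshold and 133 at 4-fold, and to 410 with array 1 alone. The age difference of Aire-induced genes went from -0.46 to -0.282 with genes chosen in perinates and to -0.384 with arrays centred on their median.

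Leaving out 1 array gave 2083 to 2768 genes for age in WT GFP+ cells, 1839 to 2469 for KO in adults, 2400 to 3684 for KO in perinates and 52 to 216 for the difference of KO effects. The ranges were 5283 to 5605 and 5044 to 5932 for GFP+ against GFP- in adults and perinates, 2265 to 2865 for their difference, 5327 to 6135 for age in GFP- cells, 2563 to 3209 for age in KO cells, and -0.492 to -0.426 for the age difference of Aire-induced genes. Without a perinate GFP- array, the lone remaining one was assumed to vary like the other groups, as was perinate KO array 1 when alone. A named gene kept its side of the threshold without 1 array in 1524 fits and lost its call in 40.

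Of 252 list tests 112 were called, 24 with an estimated correlation, 155 with fry, which asks a different question, and 113 with the block on the adult replicate numbers. Beside the lists whose loss is given with their values elsewhere, testis for KO in perinates (adjusted p = 0.0264) and MHCII-low epithelium for GFP in perinates (0.0445) lost their call with quantile normalization (0.152 and 0.056) and with an estimated correlation (0.13 and 0.313), fetal growth for KO in perinates (0.0303) with an estimated correlation (0.384), and dissociation stress for age in KO cells with fry (0.0874). The replicate block, where the numbers pair the arrays, gave 6243 genes for GFP+ against GFP- in adults and 2816 for its difference with age, and it changed no other call of a named gene, nor of a list besides the medullary regulators. Across ages a pairing by number is unsettled. Deviations correlated at 0.033 and 0.19 in WT GFP+ and 0.039 to 0.059 in KO cells. Perinate KO array 2 correlated better with adult KO array 3 (0.05). The replicate block there gave 1730 genes for age in WT GFP+ cells, 3324 for age in KO cells and 15 for the difference of KO effects, and 15 named genes lost a call. Signal over background limits the size of losses without Aire, since 579 of the 606 Aire-induced genes lay below the 60th percentile on at least 1 KO array.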

Other observations

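The tests here are those fixed beforehand, while the salivary transcripts of a single array were chosen after their values were seen. In WT GFP- cells, perinates had less of the differentiated epithelial transcripts that adults carry there. Of 12 keratinisation transcripts 9 were lower (9 adjusted over the list alone, camera adjusted p = 0.000229; adjusted p = 0.266 with an estimated correlation), led by Krt10, a keratin of differentiated skin layers, which was 8.65-fold lower at 274.7 against 2356 ± 202 (SD, n = 3). All 6 milk and seminal transcripts were lower (adjusted p = 0.00067; adjusted p = 0.125 with an estimated correlation), with the trypsin inhibitor Spink1 11.6-fold and Csn1s1 5.19-fold lower. Of 16 brain transcripts 11 were lower (adjusted p = 1.86e-05; adjusted p = 0.0803 with an estimated correlation), with Resp18 11.8-fold and Syt1 6.19-fold lower, the latter at 688 against 4268 ± 607. Of 19 liver transcripts 10 were lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 0.000885; adjusted p = 0.17 with an estimated correlation), with Apoc3 8.36-fold lower. Markers of dendritic cells and macrophages were lower in 6 of 9 (adjusted p = 0.00706; adjusted p = 0.186 with an estimated correlation), class I presentation in 6 of 13 with 1 higher (adjusted p = 0.0282; adjusted p = 0.332 with an estimated correlation) and medullary regulators in 6 of 12 with 2 higher (adjusted p = 0.0355; adjusted p = 0.369 with an estimated correlation). The fetal growth list had 5 of 9 higher and 1 lower without a call (adjusted p = 0.057), and Mest was 5.53-fold higher.

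In perinates, GFP+ cells had more of the milk transcripts, class II presentation and chemokines than GFP- cells. Of 6 milk and seminal transcripts 5 were higher (adjusted p = 0.000671; adjusted p = 0.125 with an estimated correlation). The casein Csn2, whose KO and WT levels in adults passed no test, was 13.1-fold higher in GFP+ cells, at 4787 ± 736 (SD, n = 3) against 364.6. Of 13 class II transcripts 8 were higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.00592; adjusted p = 0.151 with an estimated correlation), with H2-Ob 5.25-fold and the protease Ctss 3.88-fold higher. Of 10 chemokines 8 were higher and 1 lower (adjusted p = 0.00901; adjusted p = 0.0836 with an estimated correlation), with Ccl22 7.53-fold and Ccl17 4.93-fold higher. Interferon-response transcripts had 7 of 12 lower and 1 higher without a call (adjusted p = 0.0661). Between ages in KO cells, 5 of 16 brain transcripts were lower in perinates, among them Resp18 3.21-fold and Pcp4 2.71-fold. There, 4 of 7 transcripts tied to Fezf2 were lower, and Fezf2 itself differed by -0.12 on the log2 scale (adjusted p = 0.63). Tuft cell markers were lower in 5 of 12 (6 adjusted over the list alone, adjusted p = 0.0131; adjusted p = 0.469 with an estimated correlation), with Plcb2 2.03-fold lower, and dissociation-stress transcripts in 1 of 13 (adjusted p = 0.0372; 0.512 with an estimated correlation and 0.0874 with fry).

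Perinate GFP- array 1 stood apart from array 2 in transcripts of salivary and airway secretions. Bpifa2 read 10680 on array 1 and 71.72 on array 2, Car6 799.8 and 52.76, Mucl2 4065 and 286.7, Scgb2b27 291.2 and 15.2 and Bpifa1 3330 and 778.9. On the other 15 arrays Bpifa2 read 35.98 to 461.9, Car6 34.93 to 479.8, Mucl2 28.2 to 4759, Scgb2b27 13.06 to 171.4 and Bpifa1 88.92 to 6376, so array 1 exceeded every other array in Bpifa2, Car6 and Scgb2b27 and not in Mucl2 or Bpifa1.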
